A study of Mus musculus with 15 samples.

How the data were processed

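RNA of a treated mouse lymphoid ES (embryonic stem) cell line was compared with RNA of the same line left untreated on 15 two-colour cDNA arrays. Per the labels, each array held both RNAs, with the treated RNA in Cy5 on 8 arrays (numbered 1 to 8 in the sample titles) and in Cy3 on 7 arrays (9 to 15), the latter being dye swaps. The labels name neither the treatment nor its dose or duration, and they do not say how many cultures were grown or which arrays share RNA. Their protocol text speaks of organs and of a reference pool from control animals, wording that does not match a cell line; the channel names, which give the treated and the untreated line, were followed here. All 15 arrays form 1 group, and the deposited ratio against 0 was the test. The p-values therefore measure the spread between arrays, and if dye swaps repeat the same RNA extracts, they are too small. If 1 pool of untreated RNA served all arrays, which the labels do not settle, the spread of the control RNA is left out as well.

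The values are log2 ratios of the 2 channels as the authors deposited them, for 20205 probes on each array. The log2 scale was read from the values, and the normalization, background correction, spot filter and direction of the ratio are not given in the sources used here. Scanner intensities were not analysed here, so the signal over background of a spot is unknown. Column medians lay between -0.019 and 0.063 and column standard deviations between 0.35 and 0.82 (log2). On each array, 3.61 to 16.1% of the values equalled, within 0.0015, the log2 of a ratio of whole numbers up to 6 plus 1 constant of that array, against 1.25 to 2.06% around a shifted constant. One shift per array thus fits these values, and a correction that varies with spot brightness would not leave them in place. Spots whose signals are a few whole units give such values, and they are called dim below. Between 202 and 853 values per array were missing.

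A further 1999 values at 1223 probes had an absolute log2 ratio above 10 and equalled the log2 of 100000 plus the array constant, or minus it. They were read as placeholders for a channel at 0, which are no measurements, and were set missing; this step was chosen after seeing the data. All 1117 placeholders on arrays with the treated RNA in Cy5 were above 0, and all 882 on the dye swaps were below 0.

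The direction of the ratio had to be read from the values. The rule fixed beforehand used the median Pearson correlation over probes between arrays of opposite dye orientation: below -0.1 the dye swaps were to be turned, above 0.1 the values were to be taken as deposited, and in between each orientation was to be reported on its own without a direction. That median was -0.128 with the placeholders in and -0.058 without them, so the rule's outcome depended on values that are not measurements, and without them it left the direction unsettled. Each orientation is therefore reported on its own. In addition, a joint fit of the 15 arrays as deposited was chosen as the main one after seeing the data, for 2 reasons. The sign of the placeholders is what a ratio of Cy5 over Cy3 with an empty Cy3 channel gives after the swaps were already turned, so the deposited ratio is likely treated over untreated; Cy5 over Cy3 is a convention, and the file alone does not exclude the inverse. Pairs of probes of one gene also resembled each other in the mean of both orientations and not in their difference. Signs below are those of the deposited ratio, and counts with the swaps turned are given beside them.

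Gene names came from the platform annotation supplied with the value table. It gave 1 symbol for 13891 probes, several for 5 and none for 6309; 13855 identifiers were matched to a RefSeq table (GRCm38.p6) to update symbols. These probes stand for 9834 genes, 2969 of them with several probes, and the log2 ratios of a gene's probes were averaged on each array. No genome coordinates are given because the build behind the clones is not given in the sources used here.

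Probes and genes with values on at least 4 arrays of each orientation were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no further normalization. The model held the mean of both orientations, called the treatment estimate. It also held 0.5 times their difference (treated in Cy5 minus treated in Cy3), called the dye effect. All tests were two-sided unless stated, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. On simulated data with 19863 probes and 15 arrays, the fit recovered 52% of 100 probes shifted by 0.5 and 90% of 100 probes shifted by 1 (log2). All had the right sign, and there were 8 false calls. The simulated noise was independent and of equal spread on all arrays, with the same shift on each. The real arrays differed in spread and gave far fewer calls, so these shares may overstate the recovery. The median standard error of a probe was 0.099 (log2), and the number of arrays limits the precision.

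For gene lists, 36 lists of pathways and cell type markers fixed beforehand, each with at least 5 measured genes, were tested with camera (limma) at a preset inter-gene correlation of 0.01, again with a correlation estimated from the data, and with fry, which was run on the 8297 genes with values on all 15 arrays. Named genes followed a rule fixed beforehand: fewer than 5 genes passed in either direction, so the 5 with the smallest p in each direction are named, passed or not. No list member passed over all genes, so other named members were chosen after their values were seen, as were the called probes of Litaf and Cbfa2t3.

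The alternatives set before the data were examined covered centring, scaling and quantile normalization, filters on missing values, a robust prior, the dye term, each orientation alone, pairing of arrays by title number, array weights, effect size thresholds, the set test and the rule for several probes. Alternatives added after seeing the data were the placeholders left in, the dye swaps turned, dim spots left out, camera on the genes fry was run on, and 3 sets of arrays defined by technical properties. Set C held arrays 7, 8 and 15, where under 5% of values were dim; set B held arrays 5, 6, 11 and 13, with an array constant below 0 for Cy5 over Cy3; set A held the other 8. Each set contains both orientations. Figures were drawn with matplotlib 3.10.9.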

Results

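Gene expression of a treated mouse lymphoid ES cell line was set against the same line without treatment on 15 cDNA arrays carrying 20205 probes, 8 with the treated RNA in Cy5 and 7 with it in Cy3. ES cells are pluripotent cells from the early embryo; what makes this line lymphoid, and what the treatment was, the labels do not say. The question was which genes change their RNA level upon treatment. Between 19213 and 19973 probes per array gave a measured value. A log2 ratio above 0 likely means a higher level in the treated RNA, on the reading of the deposited ratio as treated over untreated; this reading was chosen after seeing the data.

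The genes Dnaaf2 and Ezh2 lay above 0 and Alas1 and Slco4a1 below 0, and no other gene of 9720 passed limma's test. Dnaaf2, an assembly factor for the dynein arms of cilia, had a treatment estimate of 0.52 ± 0.07 (SE, n = 15 arrays; adjusted p = 0.0149) and was above 0 on 14 arrays. Ezh2, the histone methyltransferase of a Polycomb repressive complex, was at 0.44 ± 0.07 (adjusted p = 0.0164) and above 0 on all 15. Alas1, the entry enzyme of haem synthesis, was at -0.33 ± 0.05 (adjusted p = 0.0149) and below 0 on all 15 arrays. Slco4a1, an organic anion transporter, was at -0.42 ± 0.06 (adjusted p = 0.0180) and below 0 on 14. These estimates correspond to less than a doubling of the ratio in either direction. At an unadjusted p under 0.05, 682 genes passed where chance alone gives 486.

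Of the genes named by smallest p, the other 6 did not pass limma's threshold. Above 0 these were Cebpd, a transcription factor of the C/EBP family, at 0.34 ± 0.06 (SE; adjusted p = 0.0558), Stat5a, a transcription factor of cytokine signalling, at 0.26 ± 0.05 (adjusted p = 0.0992), and Ankib1 at 0.30 ± 0.06 (adjusted p = 0.128). Below 0 they were Tnfaip2, a gene induced by tumour necrosis factor, at -0.34 ± 0.06 (adjusted p = 0.0599), Glul, glutamine synthetase, at -0.24 ± 0.04 (adjusted p = 0.0992), and Mxd1, a partner of Max that opposes Myc, at -0.49 ± 0.10 (adjusted p = 0.0992). Stat5a was above 0 on all 15 arrays, and Ankib1 on 12.

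**Figure D1:**
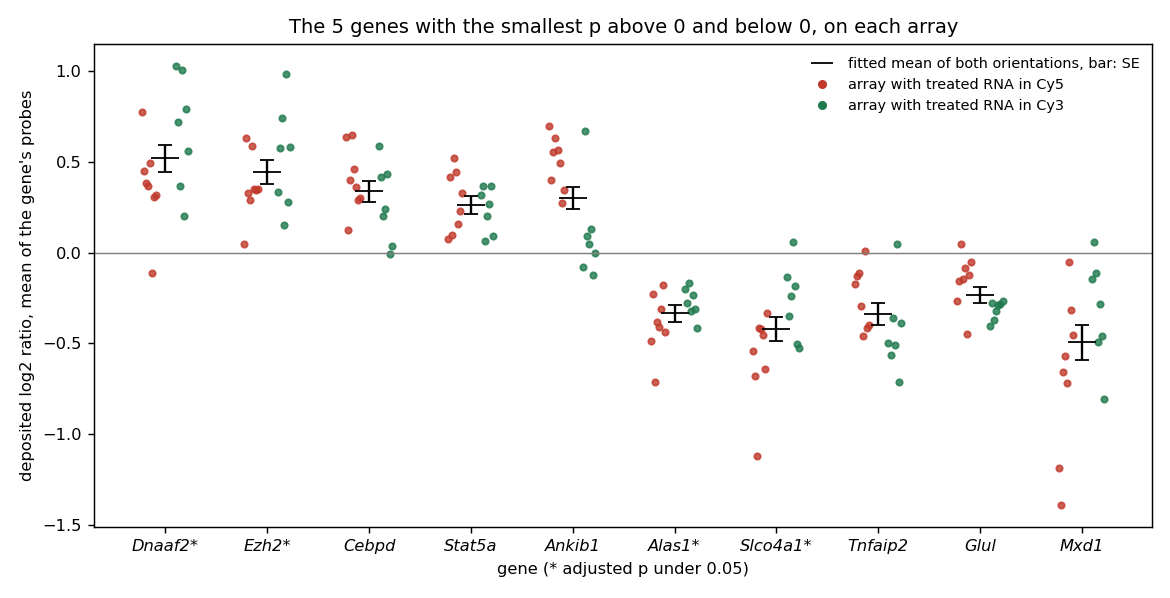
Deposited log2 ratio (vertical axis) of the 10 genes named by smallest p (horizontal axis) on each array, coloured by the dye of the treated RNA, with the fitted mean of both orientations and its SE in black. Alas1 lies below 0 and Ezh2 and Stat5a above 0 on all 15 arrays, and Ankib1 averages 0.50 on arrays with the treated RNA in Cy5 and 0.10 on the dye swaps.

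On the level of single probes, 10 of 19863 passed limma's threshold, 5 above 0 and 5 below, with 1365 at an unadjusted p under 0.05 where chance gives 993. Of the 5 above 0, 2 belong to Dnaaf2, at 1.05 ± 0.10 (SE; adjusted p = 0.000239) and 0.53 ± 0.09 (adjusted p = 0.0299); the remaining probe was at -0.02 ± 0.09, so the probes of this gene disagree. With its 4 dim values left out, the probe of Dnaaf2 at 0.53 was at 0.49 ± 0.10 and did not pass (adjusted p = 0.209 in limma). One belongs to Ezh2, and 2 are unnamed here, at 0.50 ± 0.05 and 0.60 ± 0.10. The 5 below 0 belong to Alas1, Slco4a1, Glul (-0.35 ± 0.05), Litaf (-0.51 ± 0.07) and Cbfa2t3 (-0.42 ± 0.06). Litaf encodes a factor induced by lipopolysaccharide and Cbfa2t3 a transcriptional corepressor. The second probe of Litaf was at 0.25 ± 0.15 and the further probes of Cbfa2t3 at -0.26 ± 0.12 and -0.06 ± 0.12, and the averages of these genes did not pass (adjusted p = 0.764 and 0.369 in limma). The second probe of Glul was at -0.12 ± 0.07 and did not pass (adjusted p = 0.750 in limma). Ezh2, Alas1 and Slco4a1 have 1 probe each under their symbol, so no second probe could check them.

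Leaving out each of the 15 arrays in turn, 12 of the fits called 4 or more genes and 3 called fewer, and between 4 and 10 of the 10 probes were called again. With the treated RNA in Cy5 alone or in Cy3 alone, limma called 0 probes and 0 genes. At an unadjusted p under 0.05 there were 2646 and 2794 probes, where chance gives 993. For genes there were 1273 and 1414, where chance gives 486. These fits have no dye term, so the excess can hold dye effects as well as treatment. Without arrays 7, 8 and 15, which correlated with any other array at r = 0.083 at most over probes, 2 probes and 0 genes passed. Without array 10 the count of genes was 0, without array 11 it was 2, without array 14 it was 3 and without array 6 it was 7. The gene Ezh2 did not pass after quantile normalization (adjusted p = 0.0549 in limma) or after scaling of the arrays (adjusted p = 0.0903). Without array 5 or array 8, 4 probes passed; without array 2 or array 15, 5 passed, and without array 11, 6 passed. Within the array sets A, B and C the estimates were 0.69, 0.24 and 0.43 for Dnaaf2, 0.33, 0.67 and 0.47 for Ezh2, -0.37, -0.28 and -0.36 for Alas1, and -0.46, -0.32 and -0.51 for Slco4a1. Each had the sign of the joint fit, while no gene passed within a single set. These genes were picked on the same 15 arrays, so their shared sign is not an independent check. Over all genes, the sign was shared in 53.2% between sets A and B, 51.3% between A and C and 47.7% between B and C.

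Among the 36 gene lists, 4 passed camera's test, all below 0: markers of myeloid cells, oxidative stress genes under NRF2, NF-kB and inflammatory genes, and interferon response genes. Of 25 measured myeloid markers, 19 were below 0, with a median of -0.067 (adjusted p = 0.00246). Camp, an antimicrobial peptide of neutrophils, was at -0.30 ± 0.09 (SE) and the complement gene C1qb at -0.18 ± 0.08; neither passed. Of 29 oxidative stress genes, 22 were below 0, with a median of -0.079 (adjusted p = 0.00454 with the preset correlation and 0.168 with the estimated one, which ends this call). Hmox1, which breaks down haem, was at -0.44 ± 0.15, the ferritin light chain Ftl1 at -0.24 ± 0.06 and the transketolase Tkt at -0.19 ± 0.07. Of 19 NF-kB and inflammatory genes, 15 were below 0, with a median of -0.049 (adjusted p = 0.0157). Of 24 interferon response genes, 16 were below 0, with a median of -0.039 (adjusted p = 0.0433); Irf7, a regulator of interferon genes, was at -0.60 ± 0.24 and Ifitm3 at -0.55 ± 0.24. No member of any list passed over all genes. Adjusted over the list alone, 3 NF-kB genes passed, all below 0: Tnfaip2, Ier3 (-0.35 ± 0.08) and Nfkbia (-0.25 ± 0.08), the inhibitor of NF-kB. None passed in the other 3 lists, adjusted over the list alone.

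The lists are described here by dye orientation. For the dye effect, the scaled difference between orientations, camera passed none of the 4. Adjusted p was 0.263 for the myeloid, 0.865 for the oxidative stress, 0.999 for the NF-kB and 0.954 for the interferon list. Differences between the lists were not tested. NF-kB and interferon medians were each below 0 on 6 of 8 arrays with the treated RNA in Cy5 and on 7 of 7 dye swaps, and oxidative stress medians on 5 of 8 and 5 of 7. The median of the myeloid markers was below 0 on 6 of 7 dye swaps but on 3 of 8 arrays with the treated RNA in Cy5, and in the fit of the latter it was 0.00925 (mean -0.011, adjusted p = 0.968 in camera). In that fit no list passed, with medians of -0.10 for the NF-kB, -0.088 for the oxidative stress and 0.025 for the interferon list (mean -0.073), and camera gave the direction below 0 for all 4. In the fit of the dye swaps alone, 5 lists passed, all below 0. These were the myeloid (median -0.12, adjusted p = 0.00691) and oxidative stress (median -0.081, adjusted p = 0.0484) lists, and ribosomal proteins, oxidative phosphorylation and histones. The NF-kB (median -0.084, adjusted p = 0.221) and interferon (median -0.058, adjusted p = 0.198) lists did not pass there. With the treated RNA in Cy5, camera gave ribosomal proteins, oxidative phosphorylation and histones the direction above 0. They are also the lists that passed for the dye effect described below, with the preset correlation. A fit of 1 orientation has no dye term, so it cannot tell treatment from dye. Without arrays 7, 8 and 15, no list passed (adjusted p between 0.081 and 0.106); the medians were then -0.045 for NF-kB, -0.040 for interferon, -0.040 for myeloid and -0.023 for oxidative stress genes. With the estimated correlation, the myeloid (adjusted p = 0.000335), NF-kB (adjusted p = 0.0308) and interferon (adjusted p = 0.0308) lists passed. The estimate, cut at 0 from below, was 0 for the myeloid and interferon lists, which is laxer than the preset 0.01. For the NF-kB list it was 0.019. With fry, run on the 8297 genes with values on all 15 arrays, only the myeloid list passed (adjusted p = 0.00360). Camera on those same genes passed all but the interferon list (adjusted p = 0.139). The interferon list missed the threshold when any one of arrays 3, 4, 5, 7, 8, 9, 10, 11 or 13 was left out (adjusted p from 0.0578 to 0.118), and without array 15 the count of lists was 6. It also missed the threshold with the looser filter on missing values (adjusted p = 0.0543), no dye term (0.0664), placeholders left in (0.0840), dim spots left out (0.112) and values on all 15 arrays (0.250). Its median was -0.017 without array 7, -0.060 without array 2 and -0.062 without array 15. The NF-kB median was -0.12 without array 1, -0.083 without array 4 and -0.080 without array 10, and the oxidative stress median -0.038 without array 7 and -0.045 without array 9. The oxidative stress median was -0.045 after quantile normalization, the interferon median -0.061 and the NF-kB median -0.073 after scaling of the arrays, and the NF-kB median -0.099 with values on all 15 arrays; these calls held.

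**Figure D2:**
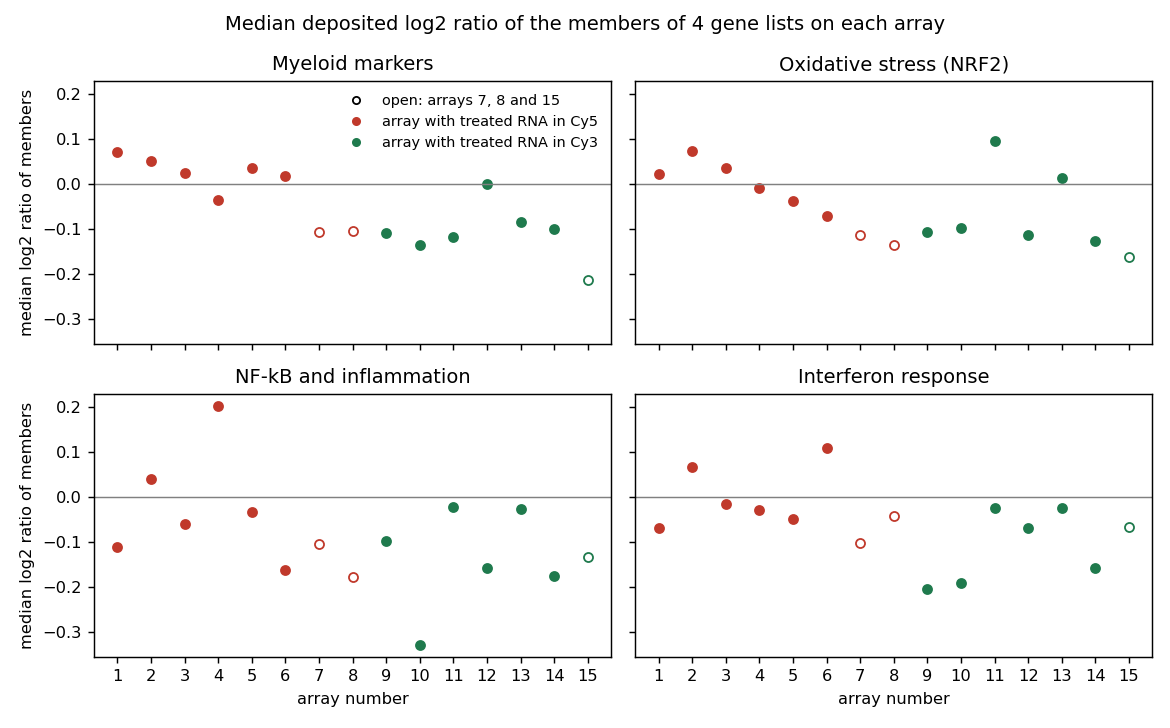
Median log2 ratio of the measured members of each of the 4 lists that passed (vertical axes) on each array (horizontal axes), coloured by the dye of the treated RNA, with arrays 7, 8 and 15 as open points. The myeloid median is below 0 on 3 of 8 arrays with the treated RNA in Cy5 and on 6 of 7 dye swaps.

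Immediate early genes were close to the threshold as a list (21 genes, 11 below 0, median -0.042), with members on both sides of 0. In camera, adjusted p was 0.0594 with the preset correlation and 0.0343 with the estimated one, which was 0 and thus laxer. The list passed without array 12 (adjusted p = 0.0316) or array 15 (adjusted p = 0.0442), and its median was -0.0051 without array 7, -0.019 without array 3, -0.065 without array 14, -0.071 without array 15 and -0.023 with dim spots left out. The median turned to 0.0046 over genes with values on all 15 arrays and to 0.0038 with placeholders left in. Adjusted over the list alone, Jun passed above 0 (0.23 ± 0.07, SE), and Ier3, Btg2 (-0.27 ± 0.06) and Klf6 (-0.36 ± 0.09) passed below 0. Glucocorticoid targets did not pass as a list (17 genes, adjusted p = 0.561). Of these, Cebpd passed above 0 and Ddit4 (-0.41 ± 0.09), Txnip (-0.31 ± 0.07) and Anxa1 (-0.24 ± 0.08) below 0, adjusted over the list alone. Among 15 p53 targets (adjusted p = 0.693 for the list), Sesn1 passed above 0 at 0.55 ± 0.11 and Ddit4 and Btg2 below 0. Among 15 TGF-beta and BMP targets (adjusted p = 0.258), Id2, an inhibitor of differentiation, passed below 0 at -0.55 ± 0.13. Both were again adjusted over the list alone. So adjusted, Mxi1 above 0 and Ddit4 below 0 also passed among glycolysis and hypoxia genes, and Jun above 0 among Wnt targets. This adjustment does not cover the 36 lists searched, and some of these genes belong to several lists.

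Markers of the identity of the line did not pass as lists, which does not show that they were unchanged. Tested were 18 of 34 pluripotency, 12 of 33 B cell and 15 of 35 T and NK cell markers. Of 18 pluripotency markers, 11 were above 0 and 7 below, with a median of 0.034 (adjusted p = 0.805 in camera). The median was 0.022 for 12 B cell markers (adjusted p = 0.805), -0.030 for 15 T and NK cell markers (adjusted p = 0.814) and -0.026 for 29 general lymphoid and blood markers (adjusted p = 0.538). Fibroblast markers, which a feeder layer would bring, had a median of 0.011 and a mean of -0.00082 over 37 genes (adjusted p = 0.980), and markers of adult organs 0.026 over 22 genes (adjusted p = 0.805). Cell cycle genes of the G1/S (27 genes, adjusted p = 0.814) and G2/M (29 genes, adjusted p = 0.805) phases did not pass either. Adjusted p-values of the lists not described lay between 0.224 and 0.980.

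**Figure D3:**
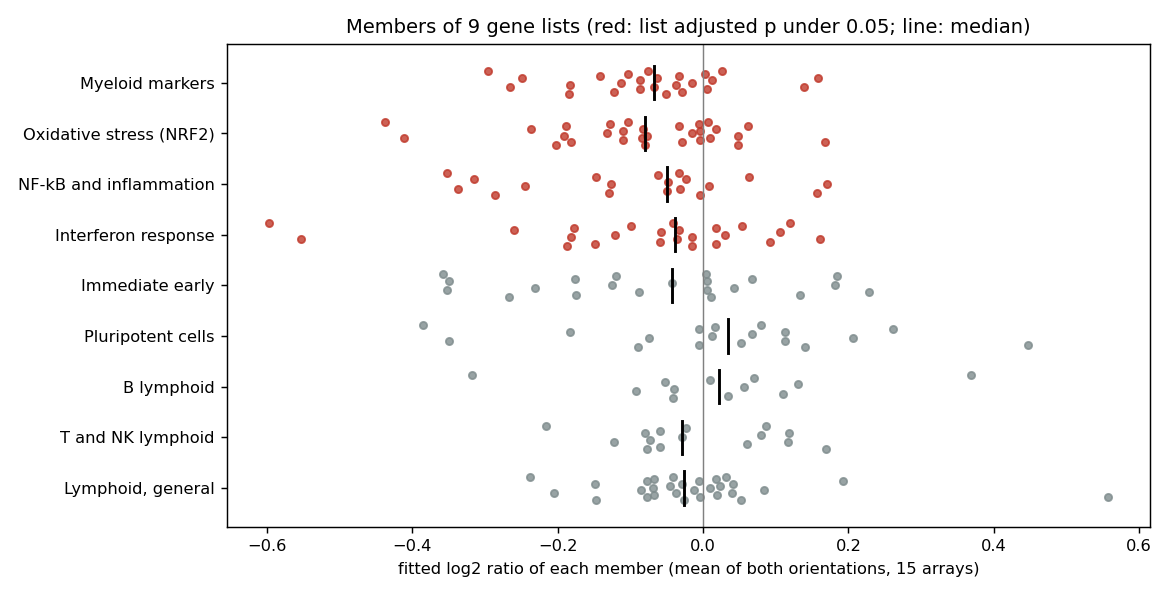
Treatment estimate (log2, horizontal axis) of each measured member of 9 gene lists (rows), with the list median as a black line and the 4 lists with adjusted p under 0.05 in red. Of 25 myeloid markers 19 lie below 0, while pluripotency markers have 11 of 18 above 0.

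The dye effect, the scaled difference between the 2 orientations defined above, was the larger component. For it, 545 probes passed limma's threshold, 393 above 0 and 152 below, and 254 genes. The probe count was 185 without array 6 and 874 without array 7. If the dye swaps were turned, these would be the treatment calls and the 10 probes above the dye calls. Lists that passed camera for this component were oxidative phosphorylation (52 genes, median 0.070, adjusted p = 0.00103), ribosomal proteins (56 genes, median 0.053, adjusted p = 0.00653) and histones (9 genes, median 0.14, adjusted p = 0.0189). None of the 3 passed with the estimated correlation (adjusted p = 0.451, 0.811 and 0.293). Over 2883 genes with a pair of fitted probes, the moderated t of both probes correlated at r = 0.094 for the treatment estimate and at r = -0.012 for the dye effect. One-sided permutation p-values over genes, which are not independent replicates, were 1e-05, the smallest that 100000 permutations can give, and 0.735. Where the first probe had an absolute t above 4, the second had the same sign in 12 of 13 genes for the treatment estimate and in 38 of 66 for the dye effect.

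**Figure D4:**
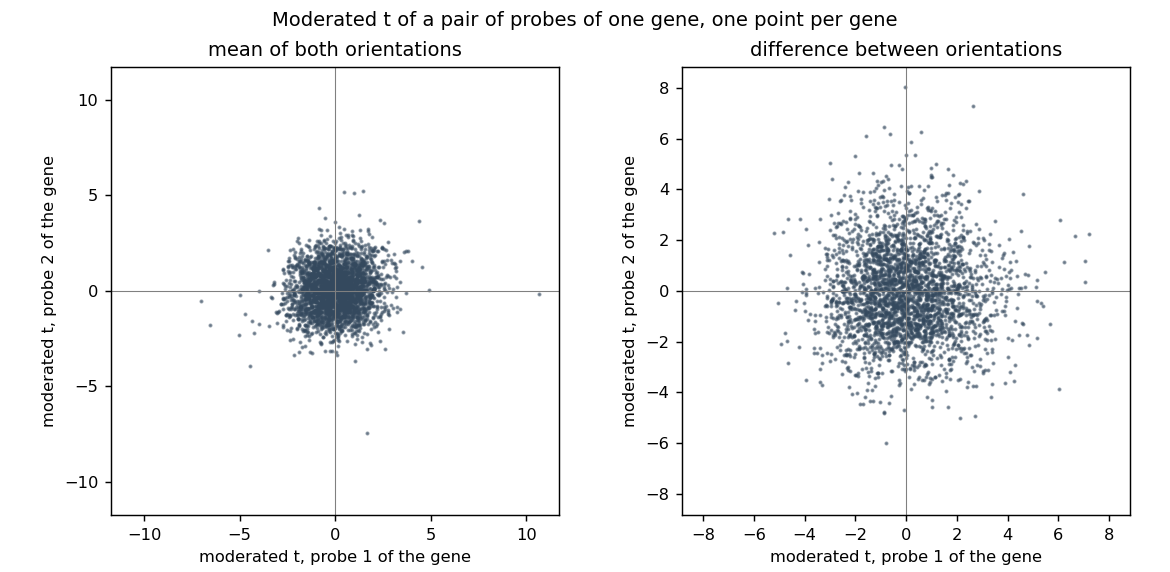
Moderated t of the second against the first fitted probe of a gene, 1 point for each of 2883 genes, for the mean of both orientations (left, r = 0.094) and for the difference between orientations (right, r = -0.012). The points on the right spread farther from 0 without lying along the diagonal.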

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

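Centring, scaling, quantile normalization, a looser filter on missing values, a robust prior, no dye term (dye effect not fitted), dim spots left out, and pairs by title number (lists not run) or array sets as a random block kept the counts within 1.5 times of 10 probes, 545 probes with a dye effect, 4 genes and 4 lists; the interferon list lost its call with the looser filter, no dye term and dim spots left out (adjusted p = 0.0543, 0.0664 and 0.112). Sizes moved more: the oxidative stress median was -0.045 after quantile normalization, the interferon and NF-kB medians -0.061 and -0.073 after scaling, and the NF-kB median -0.099 with values on all 15 arrays. Ifitm3 was at -0.31 with dim spots left out, and with the most measured probe Jun was at 0.11 and Klf6 at -0.57. Settings on placeholders, dye turning, dim spots, array sets and camera on the genes of fry were added after seeing the data, and causes of the shifts below were not tested unless named. Pairing has no basis in the labels, with a pair block correlation of -0.0060 over probes; averaging arrays n and n + 8 left 3 probes and 0 genes. Pairs read from the data were not run.

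Counts moved as follows. Values on all 15 arrays gave 7 genes, the most measured probe per gene 8, and placeholders left in 8. Array weights gave 23 probes, 9 of them among the 10, 1456 with a dye effect and 11 genes. An absolute log2 ratio of at least 1 left 1 probe and 0 genes, and limma's treat against 0.5 left 0 and 0. Each orientation alone gave 0 probes and 0 genes, with 0 lists for Cy5 and 5 for Cy3, of which 2 are among the 4. Fry passed 1 list, and camera on the same genes 3. Turning the dye swaps gave 545 probes, 10 with a dye effect and 254 genes, by construction. Without arrays 7, 8 and 15 there were 2 probes, 1031 with a dye effect, 0 genes and 0 lists. Within set A there were 1, 114, 0 and 0, within set B 0 of each, and within set C 0, 0, 0 and 2, with fewer arrays in each fit. Leaving out each array gave 4 to 13 probes, 185 (without array 6) to 874 (without array 7) with a dye effect, 0 (without array 10) to 7 genes and 3 to 6 lists.

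Estimates that changed sign did so mostly with the dye swaps turned. Then Dnaaf2 was at -0.15, Ezh2 -0.078, Sesn1 -0.099, Tnfaip2 0.090, Glul 0.082, Camp 0.093, S100a9 0.31, Ftl1 0.15, Txn1 0.078, Ier3 0.15, Nfkbia 0.21, Irf9 0.40, Irf7 0.0013, Ifitm3 0.033, Ddit4 0.31 and Anxa1 0.26. The list medians became 0.051 (myeloid), 0.019 (oxidative stress) and 0.0042 (interferon). With the treated RNA in Cy5 alone, S100a9 was at 0.13, Irf9 0.14, Anxa1 0.016, the myeloid median 0.00925 and the interferon median 0.025, though their means (-0.011 and -0.073) stayed below 0; with Cy3 alone, Litaf was at 0.081. Irf7 (0.085), Anxa1 (0.052) and Perp (0.12) turned within set B and Ccn2 (0.019) within set C. The immediate early median was 0.0046 over genes with all 15 values, in the all-15 filter, in fry and in camera on its genes, and 0.0038 with placeholders left in. Signal over background is not given, so the limit it sets is unknown.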

Other observations

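The tests on dim spots, on arrays 7, 8 and 15, and on pairs of probes were chosen after the results they bear on were seen. The regroupings of arrays were set before. The leaving out of other array triples had its prediction written before, but bears on a setting added after seeing the data. The array orientation was reassigned at random in 100 splits into 8 and 7 arrays, the real one included. For probes, genes and lists, the signs of the ratios were turned to follow the reassigned orientation. Only 1 split gave as many probes (10, highest other 1), 1 as many genes (4, highest other 1) and 1 as many probes with a dye effect (545, highest other 1). This argues against a random split as the source of these counts. For gene lists, 3 splits gave as many (4, highest other 4), below the limit set beforehand. Random splits thus also reached the real list count, so a random split is not excluded for the lists.

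Of the 10 called probes, 7 held no dim value on any array, which argues against dim spots as their source. The same holds for the probes of Ezh2 and Glul, the 2 with 1 dim value, which both still passed with it left out. The second called probe of Dnaaf2 was at 0.53 ± 0.09 (SE) and, with its 4 dim values left out, at 0.49 ± 0.10 over 11 arrays (adjusted p = 0.209 in limma); its call ended with fewer values and a larger SE, and for this probe the part of dim spots cannot be told apart. The treatment estimates of array sets without a shared array correlated weakly over genes, which are not independent replicates, at r = 0.077 between sets A and B, 0.031 between A and C and -0.023 between B and C. Whether these probes answer the treatment or another lasting difference between the RNAs remains open, since the labels name no treatment. If the dye swaps were not already turned in the deposited ratio, these probes would be dye calls instead. The placeholders argue against this, all 1117 being above 0 with the treated RNA in Cy5 and all 882 below 0 on the dye swaps. So does the correlation of probe pairs over genes, at 0.094 for the treatment estimate and -0.012 for the dye effect. The rule fixed beforehand left the direction unsettled without placeholders, and the inverse of the ratio is not excluded. No biological explanation was tested.

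The dye effect may be bound to the clone on the array and not to the gene. A treatment response in ratios not yet turned would appear in both probes of a gene, and the correlation over genes was -0.012. Of the 545 probes with a dye effect, 335 held no dim value on any array, which argues against dim spots, as marked here, as the source of these 335. Low signal that the mark misses was not tested. With dim spots left out, 650 probes had a dye effect. Among 1318 probes with dim values on more than 4 arrays, 0.303% had a dye effect, against 4.73% of 7085 probes with none (Fisher's exact test, p = 3.82e-20 over probes). A share of calls also falls where values are noisier, so this comparison of shares cannot decide the question. A bias that differs between clones stays open as an untested candidate explanation.

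The calls of the 4 gene lists were lost without arrays 7, 8 and 15, and it cannot be told apart whether these arrays alone carry the shift. Without them 63.5% of the 96 members stayed below 0, against 44.8% of all genes, and unadjusted camera p-values were 0.00330 (myeloid), 0.00496 (NF-kB), 0.0161 (interferon) and 0.0176 (oxidative stress), while no list passed after adjustment. The NF-kB median went from -0.049 to -0.045 and the interferon median from -0.039 to -0.040, each below 0 on 10 of the other 12 arrays. The myeloid median went from -0.067 to -0.040 (6 of 12 arrays) and the oxidative stress median from -0.079 to -0.023 (7 of 12). Fewer arrays in the fit did not account for the lost calls: of the 90 triples with the same dye balance that hold none of arrays 7, 8 and 15, 0 left no list when left out, and 2 to 6 lists passed. What keeps the question open is that the 4 lists were picked out of 36 on a fit that includes the other 12 arrays, so their values there are not an independent test.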
